A study of Homo sapiens with 4 samples.

How the data were processed

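The series held 4 samples of Kasumi-1 cells: 1 RNA library of cells infected with C/EBPα, 1 RNA library of cells infected with the MIGR1 vector, 1 HA ChIP library and 1 input library. Groups were taken from the labels. Per the labels' protocols, infected cells were sorted by GFP, RNA was extracted with TRIzol at 4 days, and libraries were made with a TruSeq RNA kit and sequenced on an Illumina instrument. Per the submitters' processing notes, TopHat2 2.0.9, HTSeq 0.9.1, Bowtie2 2.2.9 and MACS2 2.1.1.20160309 were used, with builds hg38 and hg19 named without a role. The annotation, the strand setting and the authors' test are not given in the sources used here. Loci in the table were compared with a GRCh38.p14 gene table by symbol and chromosome, and 16201 of 16214 overlapped, so coordinates are given as hg38. The ChIP libraries were not analysed here.

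The deposited values are RPKM per gene in each library, made by the authors, for 22809 genes, although the name of the table speaks of counts. The plan written before the data were examined assumed counts. For this unit it set log2 ratios with 1 RPKM added and a count of genes past 2-fold, which were used here. The deposited log2 fold change was the control over the C/EBPα library, so that genes higher with C/EBPα were below 0. In the full table the 670 genes that the authors' separate list gives as higher carried the word for lower, so direction was taken from the RPKM values. The deposited p-values and q-values are the authors' own. In all, 24 gene names had been turned into dates or numbers and were restored from the gene identifiers, of which 22443 were in the symbol table.

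Whole reads were recovered from the RPKM values. Each value followed from reads multiplied by 1 factor per library (1.050112 for the control and 0.952280 for C/EBPα), rounded to 3 decimals, and divided by a whole-number gene length and a total per library. Lengths were taken as whole within a relative tolerance of 1e-11. A single solution was found for 15662 genes. The locus length settled 1207 genes and the authors' p-value 5745, and the smallest solution was taken for the remaining 195. The totals correspond to 12445246 reads in the control and 14519177 in the C/EBPα library, so the deposited scaling amounts to total reads per library. Reads of listed genes summed to 12443171 and 14515719. A count of 0 allows 3 reads, or 0.241 RPM (reads scaled to the library total) in the control and 0.207 in the C/EBPα library. The length divisor exceeded the length of the locus in 7.14% of genes, so RPKM should not be compared between genes. Folds of recovered reads between the libraries are unaffected. The 1 RPKM filter, the log2 ratios with 1 RPKM added and the bins of mean expression do depend on the divisor. So do the counts of genes and the list medians drawn from them.

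The authors' p-values equalled those of an exact negative binomial test with a dispersion of 0.16 and a log2 library ratio of 0.3633 for 15659 of the 15662 genes with a single solution, within a relative tolerance of 1e-05. A trimmed mean of log ratios (TMM, trimming 30% of log ratios and 5% of mean levels) gave the same library ratio. That dispersion is a coefficient of variation of 0.4 for every gene. With 1 library per group it cannot have been measured between replicates.

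Genes at 1 RPKM or more in at least 1 library were compared. Intervals of folds are exact Clopper-Pearson 95% intervals of the split of recovered reads. PCR copies are not independent molecules, so intervals and floors cover counting error only. Each of 41 fixed gene lists was described by the median over detected members and by its percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. The named genes were set before the data were examined: CEBPA, the AML1-ETO complex genes, the 12 highest and 12 lowest genes by the interval bound nearest to no change with at least 50 reads in the higher library, up to 4 members of each described list in the direction of its median and 2 in the other, and 5 per direction from the authors' tables. Pseudogenes and clone names were skipped among the extremes. CAMP, MPO, CD14, TPSAB1 and TPSB2, and CEBPE in the closing section, were added after their values were seen. Genes in several lists were kept in each. Some genes that this rule selects are not reported here.

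The alternatives were scaling by TMM, median-ratio size factors, the upper quartile or the housekeeping genes, other filters, folds and pseudocounts, the mean of a list, lists without shared genes or the transduced gene, and recovered reads with intervals. Total-count scaling equals the deposited scaling and was not run apart. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9. The steps were tested on simulated data for this comparison. Reads were drawn for 20900 genes with 200 of them changed, and both read numbers came back exactly for 99.2% of the genes. The 2-fold rule found 93.0% of 100 genes changed 4-fold and 87.0% of 100 genes changed 3-fold, and called 138 of 11922 unchanged genes. The simulated libraries differed only by counting noise and the set changes, so these rates do not carry over to libraries that vary otherwise. Of 200 random lists, 10 stood apart, the share that the percentile limits set by construction.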

Results

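RNA was sequenced from Kasumi-1 cells, an established human myeloblast line that carries the t(8;21) translocation and its fusion product AML1-ETO (RUNX1-RUNX1T1). The cells had been infected with a retrovirus carrying HA-tagged C/EBPα, a transcription factor of granulocyte development, or with the empty MIGR1 vector, and infected cells were sorted by their GFP 4 days later. There was 1 RNA library per group, so no difference given here has a replicate check. The control library held 12445246 reads assigned to genes and the C/EBPα library 14519177, as recovered from the deposited values. The series also held 1 HA ChIP library, taken 3 days after infection, and 1 input library, which were not analysed here. The authors' levels are RPKM. Log2 ratios were taken as C/EBPα over control after adding 1 RPKM to both, which understates the difference of low genes. Folds and their exact 95% intervals were taken from the recovered reads without that addition, and cover counting error only.

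The first question was whether the transduced gene was raised in the library labelled with it. CEBPA, on chromosome 19 from 33299934 to 33302564, stood at 3.08 RPKM (101 reads) in the control library and at 82.4 RPKM (3148 reads) in the C/EBPα library. This was a 26.7-fold higher level (interval 21.9 to 32.9). Reads of the endogenous transcript and of the introduced coding sequence cannot be told apart in a count per gene.

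The title of the series names LYL1 as a target that C/EBPα represses, within the complex that AML1-ETO forms with its partners. LYL1, a basic helix-loop-helix factor of that complex on chromosome 19 from 13099033 to 13103161, was lower in the C/EBPα library. It stood at 43.8 RPKM (2148 reads) in the control and 17.0 RPKM (970 reads) with C/EBPα, 2.58-fold lower (interval 2.39 to 2.79). Of the genes compared, 2.68% had a lower ratio than LYL1. LYL1 was the only one of the 8 complex genes to pass 2-fold. LYL1 is also in the list of stem and progenitor genes, of which 12 of 17 detected members were at least 2-fold lower. LYL1 was the middle one of these 17, so its log2 ratio of -1.32 is itself the median of that list. RUNX1 was 1.57-fold lower (interval 1.51 to 1.63), CBFB 1.51-fold (1.39 to 1.63), RUNX1T1 1.44-fold (1.36 to 1.52) and TCF3 1.30-fold lower (1.23 to 1.36). LMO2 was 1.2-fold lower and TCF12 1.12-fold lower. When the libraries were scaled to the housekeeping genes, TCF12 was higher instead and LMO2 was level within counting error. LDB1 was level, with 32.1 RPKM in the control and 32.0 RPKM with C/EBPα. Reads of the fusion transcript fall in RUNX1 and RUNX1T1 and were not separated from those of the unfused genes. As a list the 8 genes had a median log2 ratio of -0.39, at percentile 20.3 of random lists of the same size matched on expression, and so did not stand apart. The median was -0.51 under TMM scaling and -0.32 under median-ratio size factors. In the authors' deposited table LYL1 had a q-value of 0.622 and was in neither of their lists.

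**Figure D1:**
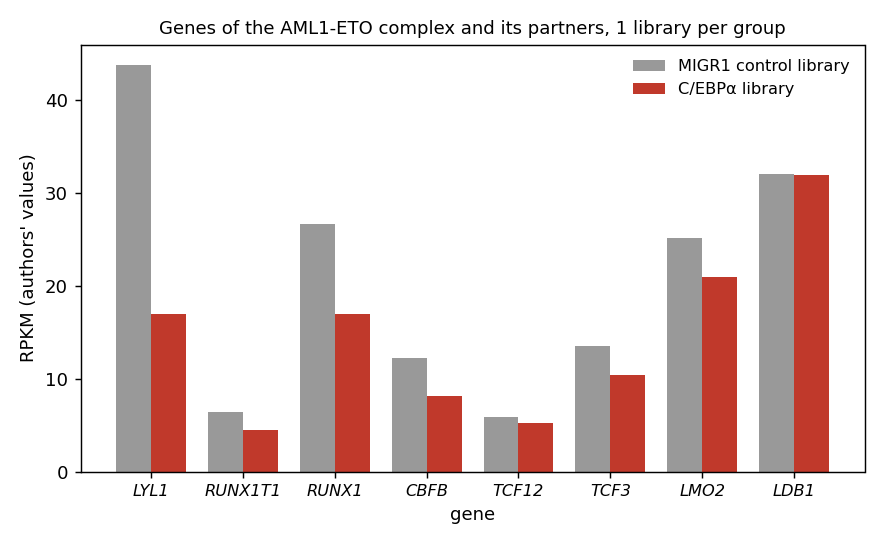
Bars give the authors' RPKM of the 8 genes of the AML1-ETO complex in the control library (grey) and the C/EBPα library (red), 1 library each, so no error bars are drawn. LYL1 went from 43.8 to 17.0 RPKM, while LDB1 stood at 32.1 and 32.0.

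Across the transcriptome, genes of neutrophil granules and of the cytosol of mature myeloid cells were far higher in the C/EBPα library, and genes of progenitor cells were lower. Of 12373 genes at 1 RPKM or more in at least 1 library, 1540 were at least 2-fold higher and 776 at least 2-fold lower with C/EBPα. At 4-fold the counts were 388 higher and 53 lower. At 16-fold they were 57 and 0. These counts use ratios with 1 RPKM added, which shrinks those of low genes. By recovered reads some genes were more than 16-fold lower, such as CD34 at 17.0-fold and DUSP27 at 35.4-fold. Scaling by TMM, a trimmed mean of ratios, gave 1293 higher and 1015 lower, so the higher genes made up 56.0% of the total in place of 66.5%. It lowered the median log2 ratio of all genes from 0.04 to -0.07. Scaling to the housekeeping genes raised that median to 0.27 and gave 2231 higher and 443 lower genes, 83.4% of them higher.

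**Figure D2:**
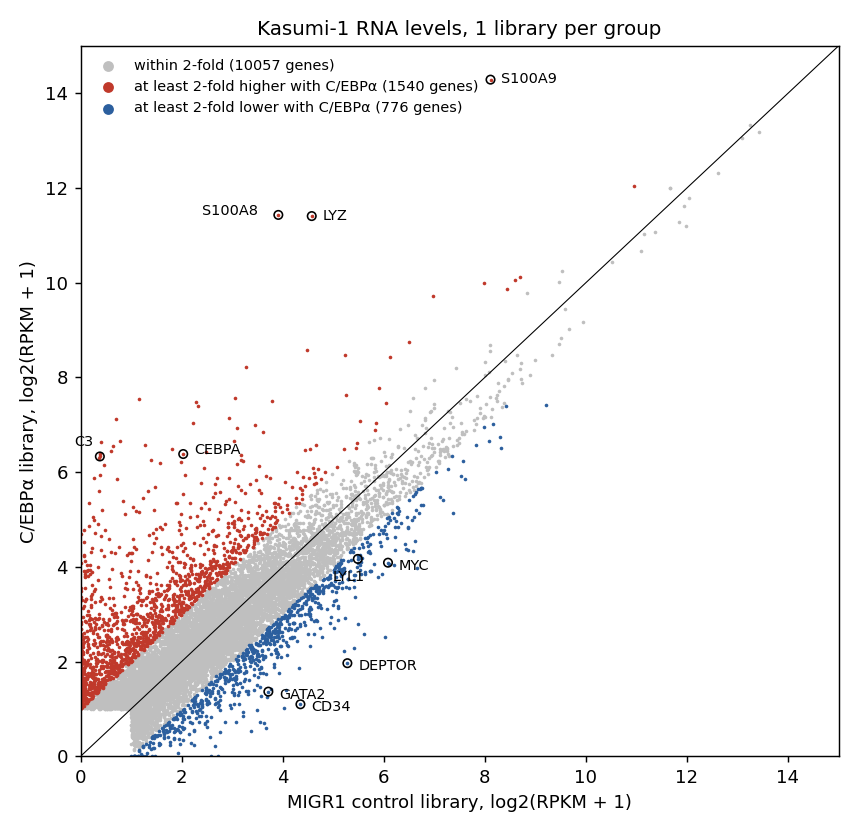
Each point is one of the 12373 genes at 1 RPKM or more in at least 1 library, with its log2(RPKM + 1) in the control library on the x axis and in the C/EBPα library on the y axis. The 1540 genes at least 2-fold higher with C/EBPα are red and the 776 at least 2-fold lower are blue, and the diagonal marks equal levels.

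Single genes were ranked by the interval bound nearest to no change, here and within the lists, which puts genes with few reads lower than their ratio would. Highest was C3, the central complement component, with 45 and 13839 reads, 264-fold higher (interval 197 to 362). HDC, which makes histamine, was 267-fold higher (182 to 409), FGR, a Src-family kinase of myeloid cells, 291-fold higher (181 to 500), and HK3, a hexokinase, 263-fold higher (166 to 445). S100A8, a subunit of calprotectin, went from 14.1 to 2761 RPKM and was 196-fold higher (173 to 224). ITGAM, the CD11b integrin chain, had 4 reads in the control and 1865 with C/EBPα, a ratio of 400 with an interval of 156 to 1468. The haptoglobin gene HP was 188-fold higher, the collagenase gene MMP8 165-fold, CKAP4 151-fold, the lactoferrin gene LTF 218-fold and the arginase gene ARG1 164-fold higher. TDRD9 had 2 and 965 reads.

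The genes with the lowest ratios included CD34. This stem and progenitor cell antigen went from 19.4 RPKM (3005 reads) to 1.14 RPKM (206 reads), 17.0-fold lower (interval 14.8 to 19.7). NPR3, a natriuretic peptide receptor, was 16.3-fold lower (13.9 to 19.2), C1orf186 13.6-fold (12.4 to 14.9) and DEPTOR, an inhibitor of mTOR, 13-fold lower (10.9 to 15.7). CD69, a lymphocyte activation antigen, was 9.78-fold lower (8.38 to 11.5). DUSP27 went from 182 to 6 reads, and GLYATL2 from 97 to 2 reads with an interval of 15.2 to 474 for the fold. ST18 was 15.1-fold lower, SHANK3 11.5-fold, KIAA1462 13.3-fold, KIF1A 12.9-fold and MIR3142HG 13.7-fold lower.

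Gene lists fixed before the data were examined asked which programs of myeloid cells differed. Of 41 lists, 39 had 3 or more detected members, and 21 stood outside the central 95% of 10000 matched random lists, 17 of them upward and 4 downward. These percentiles describe the 2 libraries and are no test between the conditions. The secondary and tertiary granule proteins stood farthest up, with a median log2 ratio of 4.56 and 15 of 16 detected members at least 2-fold higher. By the interval bound HP, MMP8, LTF and ARG1 came first, and by the log2 ratio CAMP, the cathelicidin gene, which went from 0.324 to 99.0 RPKM. Of the S100 and cytosolic myeloid proteins, 11 of 14 were at least 2-fold higher, with a median of 3.28. S100A9 went from 276 to 20005 RPKM, 72.6-fold higher (interval 69.4 to 75.9). S100A12 went from 4 to 1037 reads and the annexin gene ANXA1 was 166-fold higher (96.9 to 312). AIF1 was 1.39-fold lower.

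The primary granule proteins had a smaller median of 1.74, with 11 of 14 at least 2-fold higher. SRGN, the granule proteoglycan, was 17.9-fold higher (interval 16.4 to 19.5), and MS4A3 8.63-fold (7.73 to 9.68). DEFA4 was listed at 0 in the control against 36 reads with C/EBPα, at least 10.3-fold higher by the 3 reads that a count of 0 allows. Such floors take the reads of the C/EBPα library as exact, and the lower limit of the exact interval was 7.94. RNASE3 had 1 and 48 reads, a ratio of 41.1 with an interval of 7.04 to 1659. MPO, already at 3241 RPKM in the control, stood at 4078 RPKM. PRSS57 and SERPINB1 were 1.05-fold and 1.14-fold lower at the deposited scaling, and higher when scaled to the housekeeping genes. RNASE3 has a close relative in RNASE2, and reads shared between them could not be checked.

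The NADPH oxidase, which makes superoxide in phagocytes, had a median of 2.2 with 5 of 6 members at least 2-fold higher. CYBB was 140-fold higher (interval 103 to 195), and RAC2 6.07-fold. NCF1 was 12.9-fold higher and shares sequence with its pseudogene copies. Of the granulocyte surface receptors, 15 of 19 were at least 2-fold higher, with a median of 1.86. By the interval bound, ITGAM was followed by C5AR1, the C5a receptor, with 2 and 865 reads, FCGR3B with 2 and 230, and CEACAM1 with 4 and 265. The log2 ratios of the last 2 lay below the median of the list. At 10 RPKM or more the list no longer stood apart (median 2.52, percentile 97.0). CD33 was 1.14-fold lower, and level within counting error when scaled to the housekeeping genes. The monocyte and macrophage genes had a median of 1.60 with 4 of 8 detected members at least 2-fold higher, and of 0.33 over all 20 members in the table. They included lysozyme (LYZ), at 22.8 and 2715 RPKM and 119-fold higher (interval 111 to 128), the ficolin gene FCN1, 97.8-fold higher (51.3 to 215), and TLR2, 5.79-fold higher. CD14 stayed under 0.05 RPKM in both libraries.

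Among transcription factors of myeloid cells, 11 of 20 were at least 2-fold higher and 2 lower, with a median of 1.25. Of these 20 genes 11 are also in other lists, and the other 9 had a median of 0.35 and did not stand apart. IRF8 had 1 and 495 reads, a ratio of 424 with an interval of 75.8 to 16792. KLF5 was 35.4-fold higher (28.9 to 43.8), ID2 16.6-fold (10.5 to 27.9) and KLF6 8.68-fold (7.81 to 9.66). MYC was 4.18-fold lower (3.98 to 4.39) and VDR 4.02-fold lower (3.02 to 5.41). With 1 RPKM added the log2 ratio of VDR was -0.82, so VDR is not one of the 2 genes counted as lower. In the C/EBP family, a list that includes the transduced gene, the median was 0.73 at percentile 98.4, and 0.68 at percentile 97.8 without CEBPA. CEBPD was 14.8-fold higher (11 to 20.4), CEBPB 2.40-fold (2.03 to 2.84) and DDIT3 2.82-fold (1.98 to 4.08), and CEBPZ was 1.44-fold lower. The immediate early genes had a median of 1.53, with 9 of 16 at least 2-fold higher, and of 0.51 over all 23 members in the table. The 9 that are in no other list also had a median of 0.51 and did not stand apart. In the whole list KLF2 (13.2-fold), KLF6, EGR1 (8.15-fold) and BTG2 (13.2-fold higher) came first by the interval bound, while FOSL1 was 4.77-fold and DUSP2 2.35-fold lower.

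The lysosome genes had a median of 0.71, with 11 of 29 at least 2-fold higher. The progranulin gene GRN was 5.76-fold higher, PSAP 4.80-fold, SCARB2 3.36-fold and CTSD 3.00-fold, and CTSH was 1.48-fold lower. The interferon response had a median of 0.91, and did not stand apart over all 35 members in the table (median 0.15) or at 10 RPKM (1.18). Of its 16 detected members 6 were at least 2-fold higher, among them SAMD9L (12.8-fold), IFI35 (7.25-fold) and OAS1 with 3 and 173 reads. NF-kB and inflammatory mediators had a median of 0.67. CXCL1 was 16-fold higher, CXCL3 15.8-fold and NLRP3 9.29-fold, and IL1RN had 1 and 408 reads. NFKB1 and CD83 were 1.44-fold and 1.41-fold lower. Cytokine receptors and signalling genes had a median of 0.52, with 7 of 25 at least 2-fold higher and 3 lower. By their mean of 0.32, or without genes shared with other lists (median 0.19), they did not stand apart. IL6R was 33.6-fold higher, CSF2RA 9.69-fold, EPOR 7.33-fold and the G-CSF receptor gene CSF3R 3.68-fold. KIT, the stem cell factor receptor, was 6.72-fold lower (6.37 to 7.11) and STAT5A 4.28-fold lower (4.02 to 4.56). Adhesion genes and integrins had a median of 0.41, which was 0.27 and did not stand apart at 10 RPKM or without shared genes, with ITGA9 65.7-fold, ITGA1 75.9-fold and ITGAL 52.7-fold higher, and ITGA4 3.63-fold and ITGA5 1.79-fold lower.

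The lists that stood apart downward concerned progenitor identity and growth. Of the stem and progenitor genes, 12 of 17 detected members were at least 2-fold lower and 0 higher, with a median of -1.32, which was -0.54 over all 29 members in the table. After CD34 and NPR3 came BAALC, 9.87-fold lower (interval 6.56 to 15.4), and GATA2, 7.71-fold lower (6.52 to 9.17). MYC targets and ribosome biogenesis genes had a median of -1.26, with 27 of 35 at least 2-fold lower and 0 higher. MRTO4 was 3.76-fold lower, HSPD1, a mitochondrial chaperonin, 3.42-fold, and NOLC1 3.41-fold. The G1/S and DNA replication genes had a median of -0.81, with 10 of 37 at least 2-fold lower. UNG was 3.13-fold lower, MCM4 2.94-fold, MCM2 2.79-fold and UHRF1 2.78-fold. GINS3 was 3.43-fold and RRM2 1.2-fold higher. The cytosolic ribosomal protein genes had a median of -0.70 at percentile 0.115. All 49 were lower at the deposited scaling, 1 of them by 2-fold. Their matched random lists were lower too, with percentile limits of -0.571 and -0.134, so a part of the drop was shared with genes of like expression. The median of the ribosomal list was -0.84 under TMM scaling and -0.41 when scaled to the housekeeping genes. The list stood apart under both, but a scaling moves the list and its random lists nearly together. RPL14 was 2.12-fold lower, RPLP0 1.95-fold, RPS16 1.91-fold and RPL35 1.88-fold.

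**Figure D3:**
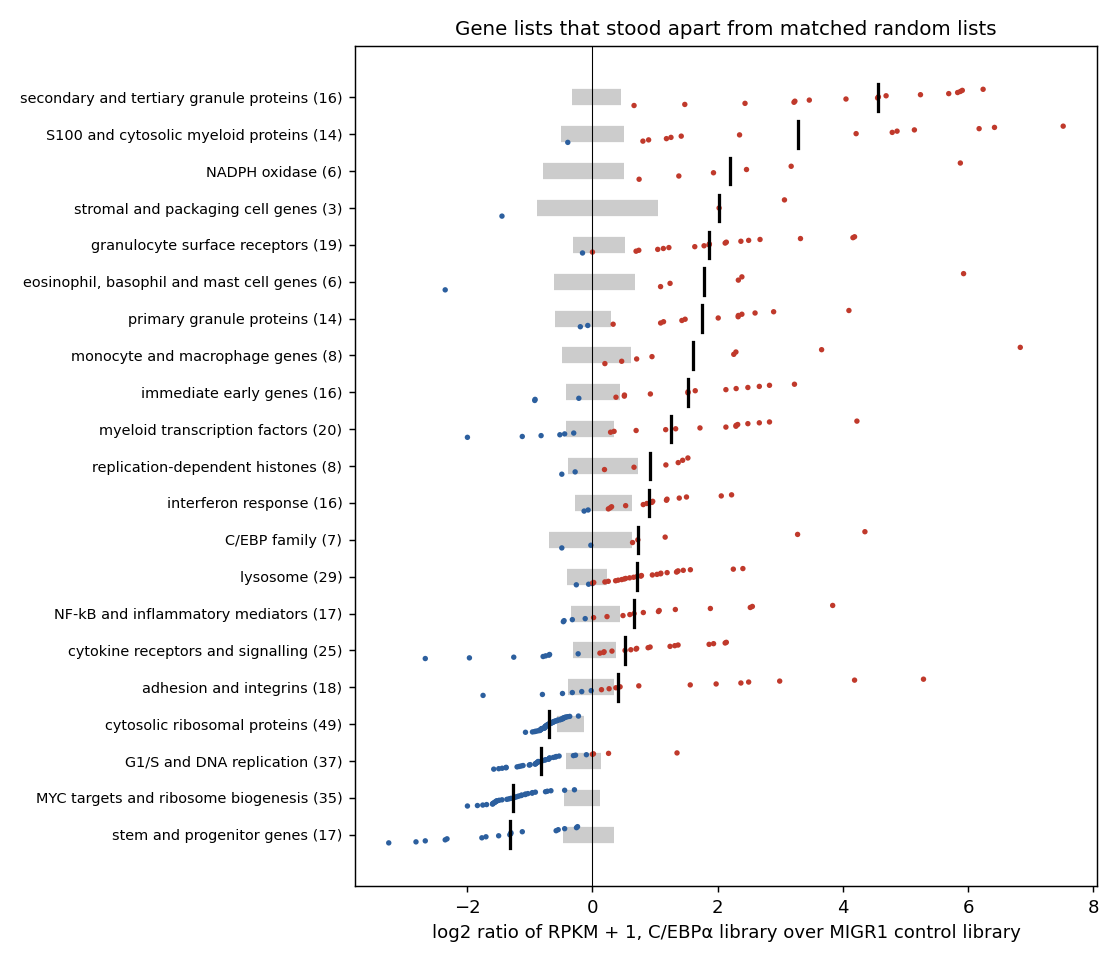
Rows are the 21 gene lists that stood apart, with the number of detected members in brackets, and the x axis is the log2 ratio of RPKM + 1. Points are genes, black bars the list medians and grey bands the central 95% of matched random lists. The medians run from -1.32 for stem and progenitor genes to 4.56 for secondary and tertiary granule proteins.

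Other lists had mixed or small differences and did not stand apart. The G2/M and mitosis genes had a median of -0.35 at percentile 7.08, and stood apart by their mean of -0.38, with 38 of 39 within 2-fold and CENPF 2.18-fold lower. The t(8;21) leukemia signature had a median of -0.46, which was -0.0475 over all 19 members in the table, and stood apart at 10 RPKM or more (-0.96), with TRH 5.61-fold, UBASH3B 2.51-fold and JUP 2.15-fold lower and PTK2B 4.19-fold and POU4F1 2.55-fold higher. The relatives of LYL1 had a median of -0.39 and a mean of -0.073. TAL1 was 5.85-fold lower (interval 4.95 to 6.95) and ID1 1.5-fold lower, and ID2, at 16.6-fold, and LMO4, at 3.65-fold, were higher. Sterol synthesis genes had a median of -0.33, with SQLE 2.18-fold, HMGCS1 2.19-fold and INSIG1 2.13-fold lower. Mitochondrially encoded genes had a median of -0.26, which was 0.03 when scaled to the housekeeping genes. Glycolysis genes had a median of -0.30 and a mean of 0.14, and stood apart without shared genes (-0.60), with SLC2A1 3.85-fold lower and SLC16A3 23.4-fold higher. Cell cycle inhibitors had a median of 0.39, which turned to -0.034 at 10 RPKM and -0.0126 without shared genes, but stood apart by their mean of 0.66. BTG1 was 11.5-fold and CDKN2D 11.9-fold higher, and RB1 1.43-fold lower. Apoptosis and BCL2 family genes had a median of 0.34, which turned to -0.41 at 10 RPKM. BCL2A1 had 3 and 383 reads, BMF was 14.5-fold higher and BCL2 was 5.46-fold lower. The p53 targets had a median of 0.15, which was 0.06 under TMM scaling, and a mean of 0.42, with TP53I3 9.85-fold and TP53INP1 6.21-fold higher and AEN 4.09-fold lower. Unfolded protein and amino acid stress genes had a median of 0.03, with TRIB3 5.05-fold higher and SLC7A5 3.21-fold and ASNS 2.53-fold lower. Lipid genes had a median of 0.00, and stood apart by their mean of 0.73 and on recovered reads (0.62), with CES1 155-fold, ALOX5 36.7-fold, ACSL1 31.1-fold and ALOX5AP 28.5-fold higher and FABP5 4.22-fold and SCD 2.99-fold lower. The last 2 medians were below 0 under TMM and upper-quartile scaling. Homeobox genes had a median of 0.65, and of 0.11 over all 19 members in the table, with 4 of 5 detected members within 2-fold.

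Markers of other cell types gave few detected genes. The eosinophil, basophil and mast cell list stood apart upward with a median of 1.79 over 6 detected members, of which HDC, RNASE2 (5.35-fold higher) and IL3RA (2.73-fold) were higher and GATA2 lower. Over all 19 members in the table the median was 0.028, and neither there nor at 10 RPKM did the list stand apart. Its tryptase genes TPSAB1 and TPSB2 stayed under 0.2 RPKM. The stromal and packaging cell list stood apart on 3 detected of the 13 members in the table, with SPARC 9.29-fold higher, VIM at 3 and 466 reads, and EPCAM 3.11-fold lower. The median was 2.02, but 0.0215 over all 13 members and 0.70 on recovered reads, where the list did not stand apart. Replication-dependent histones are no markers of a cell type. Their list stood apart with a median of 0.92 over 8 detected members. Among them were HIST1H2AC (6.92-fold), HIST2H2BE (5.32-fold) and HIST1H1C (5.02-fold higher), with only 14, 19 and 7 reads in the control. The histone list did not stand apart over all 16 members in the table (median 0.17), by its mean of 0.70 or on recovered reads (0.53). Erythroid genes had a median of 0.17, which turned to -0.66 without shared genes, with GYPC 2.28-fold lower and BLVRB 2.41-fold higher. Megakaryocyte and platelet genes had a median of 0.66, and of 0.19 over all 13 members in the table, with GP9 listed at 0 in the control and 47 reads with C/EBPα, at least 13.4-fold higher (lower limit of the exact interval 10.5). Dendritic cell genes had a median of 0.74 and a mean of 0.22 over 4 members, and a median of 0.0306 over all 11 in the table, with CLEC9A at least 20.9-fold higher against a control count of 0 (lower limit of the exact interval 16.5) and FSCN1 3.79-fold lower. B lymphoid genes had a median of -0.30 and a mean of 0.20 over 4 members, and a median of 0.0713 over all 12 in the table, with IGLL1 5.63-fold lower and CD24 14.2-fold higher. Of the T and NK lymphoid list 2 members and of the MHC class II list 1 were detected, too few for a median.

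The housekeeping genes give a measure of how far other genes lay apart, although 6 of the 29 are also in other lists. Among these, TFRC is in the MYC target list and RPLP0 in the ribosomal protein list. The 29 log2 ratios had a median of -0.29 and an SD of 0.69, from -1.37 for TFRC to 1.51 for VPS29. That median lay at percentile 50.6 of random lists matched on expression, so genes of like expression had a similar median. The median counting error of one such ratio was 0.03. ACTB was 1.91-fold higher and VCP 1.97-fold lower. This spread is no replicate error.

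The authors' deposited tables list 670 genes as higher and 63 as lower with C/EBPα, all with a q-value under 0.05. By the authors' deposited fold change, the 5 highest genes with reads in both libraries were RP11-1143G9.5, AKR1C1, CDA, IRF8 and TDRD9. The lowest were GLYATL2, DUSP27, AP001171.1 and ANGPT1, followed by a transcript with a clone name. Of the 670 genes, 485 also passed the 2-fold rule at 1 RPKM used here, and 171 lay below 1 RPKM in both libraries. Of the 63 genes, 47 passed that rule and 14 lay below 1 RPKM. CEBPA had a q-value of 2.74e-04 in the authors' deposited table, CD34 8.35e-04 and KIT 0.0405. No p-value computed from 1 library per group measures the spread between cultures.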

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

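Pseudocounts of 0.1 RPKM for every result and 5 RPKM for the counts of genes, all settings on recovered reads, the C/EBP family without CEBPA, and other assumed coefficients of variation were chosen after seeing the data. Of 420 list medians under alternatives, 397 kept their side of the percentile limits, 16 no longer stood apart and 7 newly did, and none that stood apart changed sign. All 4 scalings left every list on its side. A scaling moves a list and its random lists nearly together, so that outcome was nearly fixed in advance. These settings are among the 420 and add little to the 397. Where a call moved, the cause was not tested beyond the construction of the setting.

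Counts of genes apart, higher and lower (2316, 1540 and 776) became 5108, 2980 and 2128 at 1.5-fold and 441, 388 and 53 at 4-fold. At 10 RPKM or more they were 979, 534 and 445. A pseudocount of 0.1 RPKM gave 3663, 2424 and 1239, and one of 5 RPKM gave 736, 489 and 247. Housekeeping scaling gave 443 lower genes. Dropping the filter could not change the counts, since with 1 RPKM added no gene below 1 RPKM in both libraries reaches 2-fold. Whole reads with intervals beyond 2-fold gave 2186 to 3003 genes apart.

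Without the filter, medians that no longer stood apart were 0.028 for eosinophil, basophil and mast cell genes, 0.15 for the interferon response, 0.17 for histones and 0.0215 for stromal genes. At 10 RPKM they were 0.27 for adhesion, 1.81 for eosinophil, basophil and mast cell genes, 2.52 for granulocyte receptors and 1.18 for interferon genes, and the t(8;21) signature newly stood apart at -0.96. With means in place of medians, cytokine receptors (0.32) and histones (0.70) no longer stood apart, and G2/M genes (-0.38), cell cycle inhibitors (0.66) and lipid genes (0.73) did. Without genes shared with another list, adhesion (0.27), cytokine receptors (0.19), immediate early genes (0.51) and myeloid transcription factors (0.35) no longer stood apart, and glycolysis (-0.60) did. With 0.1 RPKM added the t(8;21) signature stood apart at -0.74. On recovered reads histones (0.53) and stromal genes (0.70) did not stand apart and lipid genes (0.62) did.

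The authors' 733 genes, of which 532 passed the size rule here, depend on the assumed spread. The same exact test, which compares these libraries and not the conditions, gave 3487 genes at an assumed coefficient of variation of 0.2, 1539 at 0.3 and 331 at 0.5. No paired analysis was possible because each group had 1 library. Depth limits genes with few control reads, whose folds have wide intervals.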

Other observations

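The tests of depth, of a single scaling factor and of the share taken by a few genes, and the last of the background tests, were chosen after the result was seen.

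The regulator CEBPE, which secondary granule genes need in normal granulocyte development, was level while those genes were far higher. It stood at 60.8 RPKM (1176 reads) in the control library and 59.7 RPKM (1348 reads) with C/EBPα, a ratio of 0.983 with an interval of 0.908 to 1.06. By share of all reads the greatest gain was that of S100A9, at 1.14 percentage points, followed by LYZ (0.70), MPO (0.40) and S100A8 (0.37). How far the whole gain was concentrated in few genes was not measured. The greatest loss was that of the elongation factor gene EEF1A1, at -0.38 percentage points, followed by the chaperone genes HSP90AA1 (-0.20) and HSPA8 (-0.19). These are differences between shares of all reads, not changes relative to a gene's own level. These genes were picked after their values were seen.

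Genes of low abundance had relatively more reads in the C/EBPα library. Of the listed genes, 2213 were at 0 in the control and 519 in the C/EBPα library, and genes at 1 to 3 RPM had a ratio of summed RPM of 1.52, against 1.05 at 10 to 100. Depth was an unlikely cause, since the C/EBPα library thinned to the control's reads had 32.6% as many genes without reads as the control (694 to 742 over 100 thinnings), and a single wrong factor does not explain a gap of 0.448 between the median log2 ratios of genes at 1 to 10 and at 10 to 100 RPM (bootstrap interval 0.406 to 0.501). An even background from genomic DNA or unspliced RNA may contribute and was left undecided, because the 3 tests of it disagree. Genes at 1 to 10 RPM gained 0.531 times (0.267 to 1.68) as many reads per kilobase as olfactory receptor and similar families, the outcome set beforehand for a background, but 10 of those 30 genes held 90.1% of their reads, so the families were not silent, and the other tests, at 0.0613 (0.0309 to 0.176) for genes below 0.3 RPM over those families and 14.6 (10.2 to 20.0) for genes at 1 to 10 over genes below 0.3, met the outcomes set against it but rest on a class whose upper bound leaves little room for added reads. A biological effect of C/EBPα on weakly expressed genes was not tested separately, with 1 library per group.

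All 49 ribosomal protein genes were lower with C/EBPα at the deposited scaling. A part of this drop was shared with other highly expressed genes. Random lists matched on expression had percentile limits of -0.571 and -0.134, and the list's median of -0.70 lay below both. The median log2 ratio was -0.172 for genes at 100 to 1000 RPM, of which 41.0% were higher. For genes at 1000 RPM or more it was -0.315, with 39.4% higher. The list lay at percentile 0.135 of random lists matched on both expression and the length divisor. That divisor exceeded the locus in 7.14% of genes, RPLP0 among them, so it is no sure measure of transcript length. A bias by transcript length was therefore left undecided. The 100 genes that gained the most share went from 6.90% to 15.7% of reads, and leaving them out moved the list's median from -0.70 to -0.56 (bootstrap interval -0.616 to -0.485). Leaving out genes picked for their gain can only raise the median, so the direction of that move was fixed in advance. The new median lies below -0.5, the bound set against a few genes taking the added reads. Its interval reaches above that bound, so whether a part of the difference comes from them was left undecided. A response of ribosomal genes to C/EBPα, beside the lower MYC level, stays open and was not tested.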
